A study of Mus musculus with 20 samples.

How the data were processed

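Medullary thymic epithelial cells (mTEC) are stromal cells of the thymus that display self-antigens to developing T cells. The labels place 20 samples in 4 groups, 2 genotypes (Trp53 wild type, WT, and a genotype labelled cHyper) by 2 sorted cell types (mTEClo and mTEChi), with replicate numbers 1 to 3 in each. By convention mTEClo and mTEChi differ in surface MHC class II or CD80; the gates used here, and what cHyper stands for, are not given in the sources used here. Per the labels' protocols, thymi came from mice of 4 to 5 weeks, the stroma was digested with enzymes, EpCAM-positive cells were enriched on magnetic beads and 75000 mTEC per sample were sorted. Per the same protocols, mRNA was made into strand-marked libraries and sequenced in pairs. Replicates 1 and 2 of each group have 2 samples with different run tags, and replicate 3 has 1 sample without a tag.

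The authors deposited 1 table of 51810 genes with 12 columns of fragment counts, 1 per group and replicate number, so the runs of replicates 1 and 2 had been combined before deposit. Per the submitters' processing notes, the genome build was mm10 and the tools were TopHat2 2.1.1, SAMtools 1.9 and featureCounts of Subread 2.0.1. The strand setting, the annotation release and any filter are not given in the sources used here, so values of overlapping and antisense genes, and of near-identical copies, are uncertain. The deposited table also holds TPM and gene lengths; TPM recomputed from counts and lengths differed from the deposited TPM by at most 0.207, and TPM entered no test. Every gene had a name, and 203 genes shared their symbol with at least 1 other gene.

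Library totals ran from 22.02 to 47.9 M fragments, at least 42.1 M in replicates 1 and 2 and at most 25.3 M in replicate 3. Replicate 3 of every group had 1049 to 1704 CPM of Xist and 0 fragments of Ddx3y, while replicates 1 and 2 had 4.13 to 7.77 CPM of Xist and at least 2745 fragments of Ddx3y. Sex, depth and run scheme therefore changed together with replicate 3 and were balanced over the groups. Nothing in the labels says that replicates are separate animals, so p-values measure the spread between these libraries.

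Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr by group), with all 12 libraries in 1 fit on group means and 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter left 28932 genes for every comparison. Of these, 931 had no fragment in any mTEClo library and could not be called there. Medians over all genes and shares of non-overlapping genes are therefore over genes with a fragment in the compared groups. These were 28001 in mTEClo, 28931 in mTEChi and 28932 between the cell types. Overlaps of calls are over genes with a fragment in both comparisons, 28000 for the genotype and 28932 for the cell types. The comparisons were cHyper against WT within each cell type, mTEChi against mTEClo within each genotype, and the difference between the genotype effects of the cell types. Levels are CPM on the TMM scale, except the Xist values above, which are CPM of the library total. Gene coordinates are those of the deposited table, on mm10.

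Before the data were examined, 27 gene lists of 333 distinct genes were fixed, together with the designs, the alternatives and the rule for named genes; 15 of these genes were not matched by symbol. The mitochondrial list had fewer than 3 tested members and was not analysed here. The other lists were tested against all other genes with camera (limma 3.58.1, preset correlation 0.01, prior count 2), with p adjusted over the lists of a comparison. Camera was repeated with an estimated correlation, and fry tested whether a list moved, on balance, one way. Counts of called list members are given over all genes tested and adjusted over the list alone.

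The rule named Trp53, Cdkn1a, Mdm2, Aire and Fezf2 always. Per pairwise comparison it took the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM over all 12 libraries and no overlap between the groups compared, leaving out predicted genes, pseudogenes and receptor segments. Of these, 2 are not reported here. It took up to 4 members of each list with the smallest p, and for the difference between effects the 4 largest each way. Which list members within the rule the text names was settled after their values were known, so totals over named genes describe the genes in the text. Outside the rule, and chosen after their values were seen, are Ltb4r2, Kank3, Klhl26, Btg2, Phlda3, Ak1, Stxbp5l, Lyz2 and Csf1r in the mTEClo genotype comparison and Ccl21a and Lyz2 in the mTEChi one. The same holds for Wfdc18 and Krtdap between the cell types of WT, for Irf7, Crp, Usp18, Rsad2 and Mx1 between those of cHyper, and for Ccl21a and Zfp36 in the difference between effects.

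A fold against a group with 0 fragments was taken against a floor of 3 fragments over the group. The other group's count was taken as exact, so this lower bound covers counting error only in the group without fragments. Intervals cover counting error only. Genes detected at equal depth were counted after thinning every library to 22023800 fragments (Python 3.11.15, numpy 2.4.6) and compared by an exact two-sided permutation test.

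The edgeR step was tested on simulated counts for 28932 genes with 200 changed genes, 50 per fold. The changed genes were drawn from those with a mean of at least 1 CPM in WT of that cell type. Recovery of genes below that level was not tested. For the mTEClo genotype comparison it recovered 32% of genes changed 1.5-fold, 76% at 2-fold, 96% at 3-fold and 98% at 4-fold, and 10 of 161 calls (6.21%) were unchanged genes. For the mTEChi genotype comparison it recovered 26%, 66%, 92% and 98%, and 13 of 154 calls (8.44%) were unchanged genes. Both shares were above the nominal 5%, but each came from 1 simulated set of counts, which does not give the rate over repeats.

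Replicate numbers were checked for pairing from the correlation of same-numbered deviations from the group means. Every pair was over 0.1 for the mTEChi genotype comparison (0.136 to 0.206) and for cHyper mTEChi against mTEClo (0.104 to 0.125), where blocked values are given beside a result that they change. Without sex-linked genes the pairs of the first ran from 0.119 to 0.163 and those of the second from 0.0872 to 0.096, none over 0.1, so the pairing in cHyper rests in part on the sex of replicate 3. The pairing comes from the data alone, and counts of calls with the block had been seen before this check was applied. The alternatives were other scalings (DESeq2 1.42.0 size factors, library totals), other filters, DESeq2 and limma-voom in place of edgeR, a fit with only the compared groups, the replicate block, a term for replicate 3, replicates 1 and 2 alone, a test against a fold of 1.5, and leaving out each library. Calls of named genes were not followed in the fit without a filter, in replicates 1 and 2 alone or in the test against a fold of 1.5. Alternatives that needed the runs of replicates 1 and 2 apart were not run, since the columns hold them combined.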

Results

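RNA of sorted medullary thymic epithelial cells was measured in 12 libraries, 3 each of WT mTEClo, cHyper mTEClo, WT mTEChi and cHyper mTEChi. The title of the series names p53 (Trp53) repression, noise in chromatin accessibility and immune tolerance. Totals ran from 22.02 to 46.46 M fragments in WT mTEClo and 25.31 to 47.93 M in cHyper mTEClo. They ran from 25.18 to 43.09 M in WT mTEChi and 23.48 to 42.94 M in cHyper mTEChi. Levels below are means ± SD over the 3 libraries of a group, in CPM. The first principal component held 85.7% of the variance.

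Trp53 itself (chromosome 11, 69580359 to 69591873, ENSMUSG00000059552) was measured first. In mTEClo it stood at 137 ± 0.959 CPM in WT and 166 ± 11.6 in cHyper, a log2 fold change of 0.27 (SE 0.083) that did not pass the test (edgeR adjusted p = 0.0553). In mTEChi it rose from 101 ± 4.6 to 134 ± 4.65 CPM (log2 0.41, SE 0.083, edgeR adjusted p = 0.020). Every cHyper library lay above every WT library of its cell type. The mTEChi call ended by the edgeR adjusted p without WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 1 or 3 (0.0895 to 0.11). In mTEClo the change passed in 5 of the alternatives. The RNA level does not report on an altered protein, so it does not check the genotype labels.

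The first comparison asked what the cHyper genotype changed in mTEClo. Cdkn1a (chromosome 17, 29090976 to 29100727, ENSMUSG00000023067), which encodes the cell cycle inhibitor p21 and is a classical Trp53 target, fell from 56.8 ± 9.29 to 30.8 ± 2.0 CPM (1.85-fold lower, log2 -0.89, SE 0.12, edgeR adjusted p = 0.000328). Most called members of the Trp53 target list moved the other way. The TNF receptor family member Eda2r rose from 1.44 ± 0.295 to 25.3 ± 1.61 CPM (17.3-fold), and Sulf2 from 53.6 ± 14.4 to 234 ± 57 (4.35-fold). Zmat3 rose from 39.7 ± 1.75 to 94.7 ± 7.89 CPM (2.38-fold), and Apaf1, a component of the apoptosome, from 50.8 ± 5.11 to 107 ± 7.72 (2.11-fold). Mdm2, the ubiquitin ligase that degrades Trp53, stood at 69.1 ± 0.858 and 73.7 ± 6.05 CPM (log2 0.093, edgeR adjusted p = 0.576). Of 39 list members tested, 16 rose and 4 fell (Cdkn1a, Btg2, Phlda3 and Ak1), or 19 and 5 adjusted over the list alone. The calls of Phlda3 and Ak1 ended by the edgeR adjusted p without WT mTEClo replicate 2 or 3 or cHyper mTEClo replicate 2 or 3 (0.0565 to 0.084) and without WT mTEClo replicate 2 or 3 or cHyper mTEClo replicate 1 or 2 (0.0526 to 0.0871). The list rose against all other genes (median log2 0.27, camera adjusted p = 3.1e-05), which ended with an estimated correlation (camera adjusted p = 0.261).

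**Figure D1:**
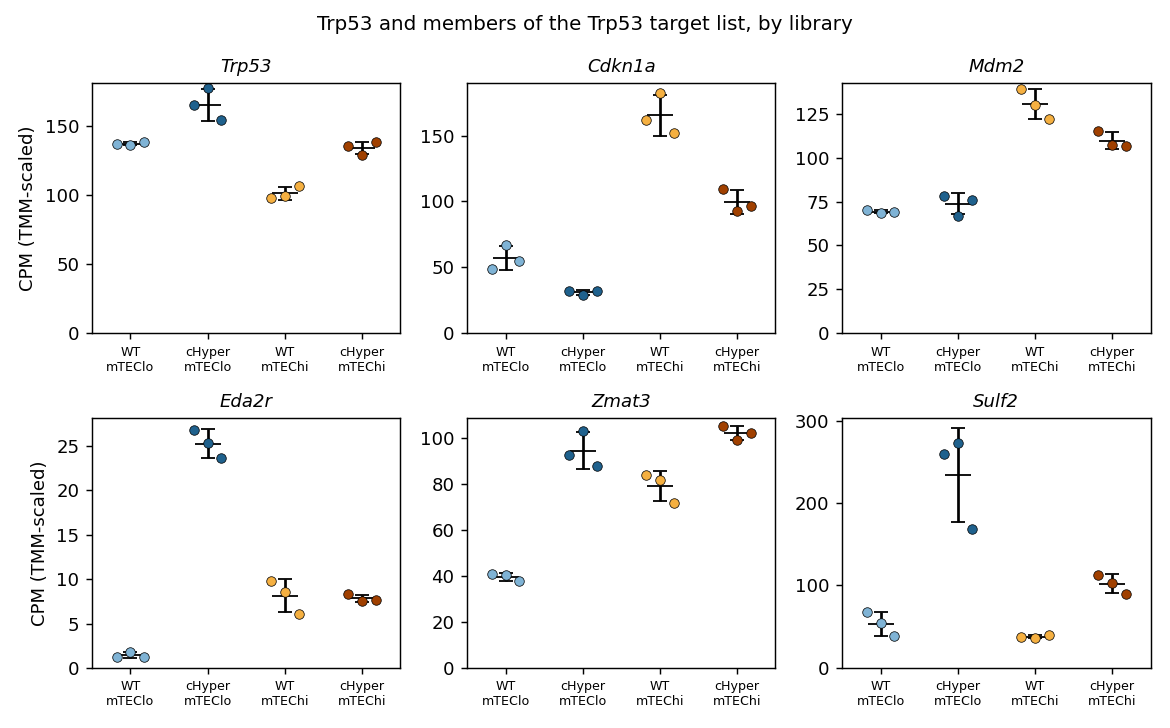
CPM on the TMM scale of Trp53 and 5 members of the Trp53 target list in the 4 groups; points are the 3 libraries of a group, the horizontal mark is their mean and the bar their SD. Cdkn1a lay lower in cHyper in both cell types (56.8 to 30.8 and 165 to 99.5 CPM), while Eda2r rose in mTEClo (1.44 to 25.3 CPM) and stood at 8.14 and 7.84 CPM in mTEChi.

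Interferon-stimulated genes fell together in cHyper mTEClo. Of 13 members 13 fell, and 13 adjusted over the list alone, with a median log2 change of -1.35 (camera adjusted p = 7.8e-18, or 0.168 with an estimated correlation). Irf7, a transcription factor of the interferon response, fell from 533 ± 69.4 to 91.7 ± 17.5 CPM (5.82-fold lower). Mx1 fell from 94.1 ± 22.6 to 16.8 ± 3.21 CPM (5.61-fold lower) and Ifit3 from 509 ± 126 to 114 ± 14.9 (4.47-fold lower). Immediate-early and stress genes fell as well, 12 of 16 over all genes and 12 adjusted over the list alone (median log2 -1.12, camera adjusted p = 7.2e-13, or 0.178 with an estimated correlation). Fosb fell from 793 ± 145 to 248 ± 8.76 CPM (3.2-fold lower), Dusp1 from 254 ± 50.3 to 84 ± 7.48 (3.02-fold lower) and Hspb1 from 117 ± 14.8 to 36.7 ± 6.22 (3.17-fold lower). Genes of this kind also respond to tissue digestion and sorting.

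Genes of mTEC subsets changed in cHyper mTEClo too. Of 12 tuft cell genes 6 fell, or 10 adjusted over the list alone (median log2 -0.71, camera adjusted p = 1.4e-05, or 0.403 with an estimated correlation). The lipoxygenase gene Alox5 fell from 97.3 ± 11.8 to 42.1 ± 11.1 CPM and the cytokine gene Il25 from 8.35 ± 2.59 to 3.08 ± 1.23. Of 11 neuroendocrine genes 4 fell (Scg2, Chgb, Pcsk1 and Stxbp5l) and Ret rose, or 7 and 1 adjusted over the list alone (median log2 -0.76, camera adjusted p = 0.00542, or 0.403 with an estimated correlation). Without cHyper mTEClo replicate 2 the median was -0.49. The calls of Stxbp5l and Ret ended by the edgeR adjusted p without WT mTEClo replicate 1 or 3, cHyper mTEClo replicate 1 or 2 or cHyper mTEChi replicate 1, 2 or 3 (0.050 to 0.151) and without WT mTEClo replicate 1 or 2, cHyper mTEClo replicate 1 or 2 or cHyper mTEChi replicate 1 (0.0607 to 0.134). Of 9 immature mTEC genes, the keratin gene Krt15 fell from 28.4 ± 5.7 to 1.75 ± 0.666 CPM (16.6-fold lower) and Ly6a from 523 ± 23.2 to 265 ± 37.9, the same count of 2 adjusted over the list alone. That list did not pass (median log2 -0.015, camera adjusted p = 0.139).

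Aire (chromosome 10, 78030022 to 78043610, ENSMUSG00000000731), the regulator of tissue-restricted antigens, rose in mTEClo from 14.3 ± 2.6 to 44.5 ± 6.46 CPM (3.12-fold, log2 1.64, SE 0.17, edgeR adjusted p = 2.4e-05). Of 15 mature mTEC genes Aire and Ciita rose and Cd80 fell, with 2 and 1 adjusted over the list alone (median log2 0.14, camera adjusted p = 0.101). The call of Ciita ended by the edgeR adjusted p without WT mTEClo replicate 3 or cHyper mTEClo replicate 2 (0.0514 to 0.0559). Cd80, a costimulatory gene, fell from 7.0 ± 2.2 to 3.43 ± 0.665 CPM. Fezf2, another regulator of tissue antigens, stood at 157 ± 5.22 and 139 ± 29.3 CPM (log2 -0.17, edgeR adjusted p = 0.511). Of 9 Aire-dependent antigens Fabp9 and Pcp4 rose and Wfdc18 fell, or 3 and 2 adjusted over the list alone (median log2 0.10, camera adjusted p = 0.996). With library totals as scaling 1 rose and 1 fell. The calls of Fabp9 and Pcp4 ended by the edgeR adjusted p without WT mTEClo replicate 1, 2 or 3, cHyper mTEClo replicate 2 or 3, WT mTEChi replicate 1 or 3 or cHyper mTEChi replicate 2 (0.0508 to 0.13) and without WT mTEClo replicate 1, 2 or 3 or cHyper mTEClo replicate 2 or 3 (0.0511 to 0.20). Of 20 liver and pancreas antigens Crp and Ahsg fell, with 3 rising and 3 falling adjusted over the list alone (median log2 -0.15, camera adjusted p = 0.707).

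The remaining subset lists did not pass in mTEClo, apart from the ionocyte genes. Of 7 secretory genes Bpifa1 rose from 17.1 ± 2.39 to 70.9 ± 24.1 CPM and Bpifb1 from 0.646 ± 0.286 to 2.14 ± 0.557, with 3 rising and 1 falling adjusted over the list alone (median log2 0.41, camera adjusted p = 0.13). Of 11 muscle genes Ttn, Actc1 and Myh8 rose and Chrna1 fell, or 4 and 1 adjusted over the list alone (median log2 0.20, camera adjusted p = 0.155). The calls ended by the edgeR adjusted p for Actc1 without WT mTEClo replicate 2 or 3, cHyper mTEClo replicate 2 or 3, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1, 2 or 3 (0.0607 to 0.169), for Myh8 without WT mTEClo replicate 2 or 3 or cHyper mTEClo replicate 1 (0.0511 to 0.0589) and for Chrna1 without WT mTEClo replicate 3 or cHyper mTEClo replicate 1 (0.0543 to 0.0682). Of 9 ciliated cell genes Dynlrb2 rose, or 3 adjusted over the list alone (median log2 0.48, camera adjusted p = 0.123), a call that ended by the edgeR adjusted p without WT mTEClo replicate 1 or 3 or cHyper mTEClo replicate 3 (0.083 to 0.097). Of 11 keratinocyte genes Krtdap fell, with 1 rising and 1 falling adjusted over the list alone (median log2 0.20, camera adjusted p = 0.557). Of 8 microfold genes Ccl6 fell, or 2 adjusted over the list alone (median log2 -0.23, camera adjusted p = 0.33), a call that ended by the edgeR adjusted p without WT mTEClo replicate 1 or 3 or cHyper mTEClo replicate 1 or 2 (0.0654 to 0.125). Of 9 enterocyte and hepatocyte genes Vil1 fell, or 2 adjusted over the list alone (median log2 -0.51, camera adjusted p = 0.0544). Of 8 cortical epithelial genes Tbata rose, or 4 adjusted over the list alone (median log2 0.35, camera adjusted p = 0.080). For the ionocyte genes edgeR called 0 of 5, 2 were at an unadjusted p under 0.05, and DESeq2 called 0 and limma-voom 0. Adjusted over the list alone 2 fell (median log2 -0.29, camera adjusted p = 0.0489, or 0.261 with an estimated correlation), a list call that ended without WT mTEClo replicate 1, 2 or 3, cHyper mTEClo replicate 2 or 3, WT mTEChi replicate 3 or cHyper mTEChi replicate 2 or 3 (0.0513 to 0.121), and the median was -0.46 without cHyper mTEClo replicate 1. With 1 library left out several lists passed camera that did not with all (adjusted p in parentheses), the secretory list without cHyper mTEClo replicate 1 (0.0198), the ciliated list without WT mTEClo replicate 2 (0.00354), the microfold list without cHyper mTEClo replicate 3 (0.035), the enterocyte and hepatocyte list without WT mTEClo replicate 1 or cHyper mTEClo replicate 3 (0.000322 to 0.00553) and the cortical epithelial list without WT mTEClo replicate 1 or cHyper mTEClo replicate 2 (0.00765 to 0.0354).

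Cell cycle genes had a median log2 change of 0.29 in mTEClo (camera adjusted p = 0.00779, or 0.652 with an estimated correlation). The camera call ended without WT mTEClo replicate 1 or cHyper mTEClo replicate 2 (0.172 to 0.708), where the median was 0.055 and 0.13, and without WT mTEClo replicate 2 the median was 0.62. By edgeR 0 of 40 were called, also adjusted over the list alone, against 7 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. Of 8 chemokines Cxcl10 fell from 571 ± 147 to 189 ± 11.4 CPM, while Ccl22 rose from 2.56 ± 1.7 to 11.8 ± 4.58 and Ccl17 rose too, with the same counts adjusted over the list alone (2 and 1; median log2 0.11, camera adjusted p = 0.996). The call of Ccl17 ended by the edgeR adjusted p without WT mTEClo replicate 1 or 3 or cHyper mTEClo replicate 3 (0.0949 to 0.115).

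Markers of other cells that a sort can hold were measured in the same way. Thymocyte genes had a median log2 change of 0.99 in mTEClo (camera adjusted p = 0.00226, or 0.589 with an estimated correlation). The median was 0.53 without WT mTEClo replicate 1 and 1.73 without WT mTEClo replicate 2. The cell cycle list moved the same way with these libraries (0.055 and 0.62), and whether its change came from mTEC or from thymocytes was not tested. By edgeR 0 of 15 thymocyte genes were called, also adjusted over the list alone, against 7 at an unadjusted p under 0.05, 1 by DESeq2 and 2 by limma-voom. Of 14 myeloid and dendritic markers C1qb fell, or 0 adjusted over the list alone (median log2 -0.0022, camera adjusted p = 0.557), a call that ended by the edgeR adjusted p without WT mTEClo replicate 1 or 2, cHyper mTEClo replicate 1, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1, 2 or 3 (0.0517 to 0.192). The lysozyme gene Lyz2 stood at 13.1 ± 3.49 and 17.6 ± 8.77 CPM. Of 8 fibroblast markers Col3a1 rose from 24 ± 2.94 to 68.4 ± 28.7 CPM, Dpt rose and Pdgfra fell from 2.73 ± 0.0941 to 0.884 ± 0.376, or 2 and 3 adjusted over the list alone (median log2 -0.31, camera adjusted p = 0.503). Of 5 erythroid genes Hbb-bt and Hbb-bs, near-identical copies, fell, as they did adjusted over the list alone (2; median log2 -0.17, camera adjusted p = 0.311). B cell (median log2 -0.076, camera adjusted p = 0.622), endothelial (-0.53, 0.0544) and sex-linked (-0.14, 0.955) lists of 5 genes each had 0 calls by edgeR. At an unadjusted p under 0.05 they had 1, 2 and 0, DESeq2 called 1, 0 and 0, and limma-voom 0 in each. Adjusted over the list alone 1 B cell gene fell, against 0 in the other lists. The endothelial list passed camera without WT mTEClo replicate 2 or cHyper mTEClo replicate 2 (0.0267 to 0.028).

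The largest changes in mTEClo by the rule for named genes included these. Cpz, a secreted carboxypeptidase, rose from 0.0388 ± 0.0354 to 41.9 ± 1.36 CPM, and Astl from 0.0312 ± 0.027 to 1.31 ± 0.31. Some genes had 0 fragments in WT mTEClo and few in cHyper mTEClo, at 0.107 to 0.224 CPM. They were higher in cHyper by at least 7.96-fold (Hbb-y, 25 fragments), 4.46-fold (Mroh7, Lce1j and Crygs, 14 each), 4.14-fold (Tectb, 13) and 3.82-fold (Ppp1r1c, 12). These genes met the mean of 1 CPM over all 12 libraries only through mTEChi. Slc18a3 had 16 fragments in WT mTEClo and 0 in cHyper mTEClo, and was at least 5.58-fold lower. Sncg, which encodes gamma-synuclein, fell from 18.5 ± 5.42 to 0.542 ± 0.0348 CPM (34.5-fold lower) and Ifi213 from 21.9 ± 1.26 to 0.82 ± 0.331. Ms4a10 fell from 5.53 ± 0.556 to 0.271 ± 0.167 CPM, Gpr20 from 1.52 ± 0.207 to 0.073 ± 0.00732 and Ms4a4d from 6.15 ± 1.13 to 0.328 ± 0.11. Adam7 had 23 fragments in WT and 1 in cHyper, a ratio of 24.1 (95% counting interval 3.91 to 992). By the edgeR adjusted p, the call of Crygs ended without cHyper mTEClo replicate 2 (0.059), that of Slc18a3 without WT mTEClo replicate 2 or 3 or cHyper mTEClo replicate 1 or 2 (0.0694 to 0.0828) and that of Adam7 without WT mTEClo replicate 3 or cHyper mTEClo replicate 1 or 2 (0.0646 to 0.104). Among tuft cell genes Chat and Sh2d6 lost their calls without WT mTEClo replicate 3 or cHyper mTEClo replicate 2 (0.0554 to 0.0639) and without WT mTEClo replicate 3 or cHyper mTEClo replicate 2 (0.0606 to 0.082).

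Some calls of named genes in mTEClo ended with all libraries kept. With only the compared groups in the edgeR fit those of Sh2d6 (0.0552), Ret (0.0698), Ccl17 (0.123), Pcp4 (0.0749), Fabp9 (0.121), Ahsg (0.0609), C1qb (0.215), Ak1 (0.0831), Stxbp5l (0.0858), Ccl6 (0.0759), Dynlrb2 (0.0607), Chrna1 (0.0966), Actc1 (0.114) and Myh8 (0.0588) ended (adjusted p in parentheses). By the limma-voom adjusted p those of Ccl17 (0.144), Pcp4 (0.282), Fabp9 (0.301), C1qb (0.152), Chrna1 (0.106), Actc1 (0.0579) and Myh8 (0.0748) ended. With DESeq2 size factors the edgeR adjusted p ended the call of Actc1 (0.0556), and with library totals those of Fabp9 (0.0501) and Actc1 (0.0594).

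In all, 2651 of 28932 genes were called between the genotypes in mTEClo by edgeR, 1310 higher and 1341 lower in cHyper, of which 527 and 573 changed at least 2-fold by the fitted value. The groups did not overlap in 25.2% of genes with a fragment, against 10% by chance. Replicates 1 and 2 alone called 2050 genes, of which 1923 (93.8%) had the same direction in replicate 3, which holds too few libraries for a test of its own.

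The second comparison asked the same of mTEChi, the subset that displays most tissue-restricted antigens. Of 9 immature mTEC genes 4 rose in cHyper (Krt14, Krt5, Itgb4 and Ccl21a) and Krt15 fell, or 7 and 1 adjusted over the list alone (median log2 0.44, camera adjusted p = 6.6e-05, or 0.248 with an estimated correlation). The basal keratin genes Krt14 and Krt5 rose from 241 ± 17.8 to 543 ± 55.7 CPM (2.25-fold, edgeR adjusted p = 0.000215) and from 680.2 ± 108 to 1336 ± 318 (1.96-fold, edgeR adjusted p = 0.0101). The chemokine gene Ccl21a, which has near-identical copies, rose from 356 ± 37.7 to 732 ± 253 CPM, a call that ended by the edgeR adjusted p without WT mTEChi replicate 1 or 3 (0.058 to 0.0641). The call of Itgb4 ended without WT mTEChi replicate 1 or cHyper mTEChi replicate 2 (0.0525 to 0.0558). Krt15 fell from 33 ± 2.64 to 13.9 ± 0.619 CPM. Of 15 mature mTEC genes edgeR called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (median log2 -0.070, camera adjusted p = 0.295). Aire stood at 1919.9 ± 2.83 and 1645 ± 321 CPM (log2 -0.22, edgeR adjusted p = 0.548) and Fezf2 at 468 ± 57.1 and 446 ± 33.5 (log2 -0.070, edgeR adjusted p = 0.853).

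Cdkn1a fell in mTEChi from 165 ± 15.6 to 99.5 ± 8.98 CPM (1.66-fold lower, log2 -0.73, SE 0.12, edgeR adjusted p = 0.00418), while Mdm2 stood at 130.5 ± 8.52 and 109.7 ± 4.79 (log2 -0.25, edgeR adjusted p = 0.192). Of 39 Trp53 targets 10 rose and Cdkn1a fell, or 16 and 5 adjusted over the list alone (median log2 0.22, camera adjusted p = 0.00464, or 0.561 with an estimated correlation), and without WT mTEChi replicate 1 the median was 0.12. With DESeq2 size factors or library totals as scaling, 8 rose and 2 fell. Sulf2 rose from 37.9 ± 1.46 to 102 ± 11.5 CPM (2.69-fold), Ercc5 from 16.3 ± 1.54 to 27.7 ± 2.01 (1.7-fold), Apaf1 from 51.5 ± 4.76 to 86.2 ± 5.1 (1.67-fold) and Abhd4 from 35.3 ± 3.2 to 57.2 ± 5.29 (1.62-fold).

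Immediate-early and stress genes were lower in cHyper mTEChi as a list, with 3 of 16 falling (Fosb, Dusp1 and Egr1), or 6 falling and 1 rising adjusted over the list alone (median log2 -0.23, camera adjusted p = 0.00968, or 0.749 with an estimated correlation), and 5 fell with either other scaling. The camera call ended without cHyper mTEChi replicate 1 or 2 (0.0868 to 0.103), and in replicate 3 the mean log2 level of the list was 6.64 in WT and 6.73 in cHyper, so the fall of that mean lay in replicates 1 and 2. Fosb fell from 153 ± 25.6 to 59.2 ± 11.5 CPM. The calls of Dusp1 and Egr1 ended by the edgeR adjusted p without WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 1 or 2 (0.0574 to 0.0884) and without WT mTEClo replicate 1 or 2, cHyper mTEClo replicate 1 or 2, WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 1, 2 or 3 (0.0502 to 0.184). Of the interferon-stimulated genes Mx1 fell, or 5 adjusted over the list alone (median log2 -0.32, camera adjusted p = 0.0108, or 0.749 with an estimated correlation), and 4 fell with either other scaling. The camera call of that list ended without WT mTEChi replicate 2 or cHyper mTEChi replicate 1 (0.0773 to 0.133), with a median of -0.13 without WT mTEChi replicate 2. The edgeR call of Mx1 ended without WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 1, 2 or 3 (0.0639 to 0.113). Of 14 myeloid and dendritic markers Adgre1 fell, the same 1 adjusted over the list alone (median log2 -0.45, camera adjusted p = 0.0306, or 0.248 with an estimated correlation), and the edgeR call of Adgre1 ended without WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1 or 3 (0.0789 to 0.152). The camera call of the list ended without WT mTEChi replicate 3 or cHyper mTEChi replicate 1, 2 or 3 (0.0575 to 0.166). Lyz2 stood at 446 ± 71.2 and 434 ± 34.5 CPM. Cell cycle genes did not pass (camera adjusted p = 0.0609) but did with the replicate block (0.0377), against 0.819 without the block at an estimated correlation. The list also passed camera without WT mTEClo replicate 1, 2 or 3, cHyper mTEClo replicate 1, 2 or 3, WT mTEChi replicate 2 or cHyper mTEChi replicate 1 (0.0211 to 0.0486). By edgeR 0 of these 40 were called, with 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. In lists that did not pass, Pou2f3 (tuft), Ctsl (cortical epithelial) and Bpifa1 (secretory) rose. By the edgeR adjusted p the call of Pou2f3 ended without WT mTEChi replicate 2 or 3 or cHyper mTEChi replicate 1 (0.103 to 0.146) and that of Ctsl without WT mTEChi replicate 1 or 3 or cHyper mTEChi replicate 2 or 3 (0.113 to 0.133).

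The largest rises in mTEChi by the rule included those of the leukotriene B4 receptor genes Ltb4r2, from 1.05 ± 0.249 to 14.3 ± 1.4 CPM (13.3-fold), and its neighbour Ltb4r1, from 1.04 ± 0.0722 to 7.11 ± 1.44 (6.78-fold), whose fragments are uncertain where such genes overlap. Kank3 rose from 4.67 ± 0.725 to 33.7 ± 3.68 CPM, Snx20 from 4.38 ± 0.952 to 23.2 ± 3.75, Klhl26 from 11 ± 0.225 to 53.6 ± 1.67 and Hmgcll1 from 2.11 ± 0.48 to 8.46 ± 0.669. Pcdhb9, of a gene cluster with similar copies, rose from 0.286 ± 0.0859 to 1.38 ± 0.593, and Sgce from 0.503 ± 0.284 to 2.29 ± 0.581. Sncg fell from 136 ± 10.7 to 16.6 ± 2.95 CPM (8.19-fold lower), Rin1 from 12.2 ± 1.57 to 4.38 ± 0.764, Mansc4 from 5.53 ± 1.74 to 2.1 ± 0.329 and Anxa8 from 18 ± 2.48 to 7.23 ± 1.56. Ankrd65 fell from 1.29 ± 0.199 to 0.412 ± 0.163 CPM, a call that ended by the edgeR adjusted p without WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 1 or 3 (0.0535 to 0.0868). Ifi213 fell from 1.85 ± 0.416 to 0.692 ± 0.26 CPM, a call that ended without WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 1 or 3 (0.0918 to 0.109). Fendrr fell from 4.98 ± 1.1 to 1.91 ± 0.198 CPM, a call that ended without cHyper mTEClo replicate 1, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1, 2 or 3 (0.0576 to 0.195).

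In all, 572 genes were called in mTEChi by edgeR, 451 higher and 121 lower in cHyper, of which 93 and 35 changed at least 2-fold. With the replicate block 1251 were called, 942 higher and 309 lower. The share of higher genes was 78.8%, and 66% with DESeq2 size factors (352 higher, 181 lower) and 64.4% with library totals (335 higher, 185 lower). Without WT mTEChi replicate 1, 2 or 3 the count was 341, 316 or 323, and without cHyper mTEChi replicate 1, 2 or 3 it was 333, 321 or 296. With replicates 1 and 2 alone, edgeR called 312, of which 300 (96.2%) had the same direction in replicate 3. The groups did not overlap in 25.7% of genes, against 10% by chance.

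The genotype calls of both cell types shared more genes than independent lists would. Of 28000 genes with a fragment in both comparisons, which share no library, 212 rose in both (21.1 for independent lists) and 60 fell in both (5.75). Deviations of same-numbered mTEClo and mTEChi libraries correlated (0.093 to 0.233 in WT, 0.104 to 0.125 in cHyper). The lists were therefore not independent, and the values for independent lists are no measure of chance. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.11 and a Spearman correlation of 0.205. In mTEClo Ltb4r2 rose from 9.93 to 60.5 CPM, Kank3 from 15.6 to 53.1 and Klhl26 from 29.5 to 104 (edgeR adjusted p of 2.6e-07, 4.9e-06 and 4.3e-08).

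The genotype effect differed between the cell types for 595 genes by edgeR's test of the difference, with 327 higher and 268 lower in mTEChi than in mTEClo. Of the interferon-stimulated genes 9 of 13 differed, or 12 adjusted over the list alone, all with the lesser fall in mTEChi (median difference 1.05, camera adjusted p = 2.0e-14, or 0.145 with an estimated correlation). Of the immediate-early genes 5 differed, or 12 adjusted over the list alone (median difference 0.64, camera adjusted p = 4.2e-09, or 0.262 with an estimated correlation). Of the immature mTEC genes 5 differed upwards, or 7 adjusted over the list alone (median difference 1.1, camera adjusted p = 5.1e-08, or 0.145 with an estimated correlation). Aire differed by a log2 of -1.87 (SE 0.23, edgeR adjusted p = 0.000941), Eda2r by -4.17 and Zmat3 by -0.89. Cdkn1a (0.15, edgeR adjusted p = 0.772), Trp53 (0.13, 0.682), Mdm2 (-0.34, 0.204) and Fezf2 (0.096, 0.906) did not pass. The count was 354 without WT mTEChi replicate 2, 387 without WT mTEChi replicate 3, 354 without cHyper mTEChi replicate 2 and 382 without cHyper mTEChi replicate 3. Replicates 1 and 2 alone called 284 of the genes tested in all libraries, of which 277 had the same direction in replicate 3.

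**Figure D2:**
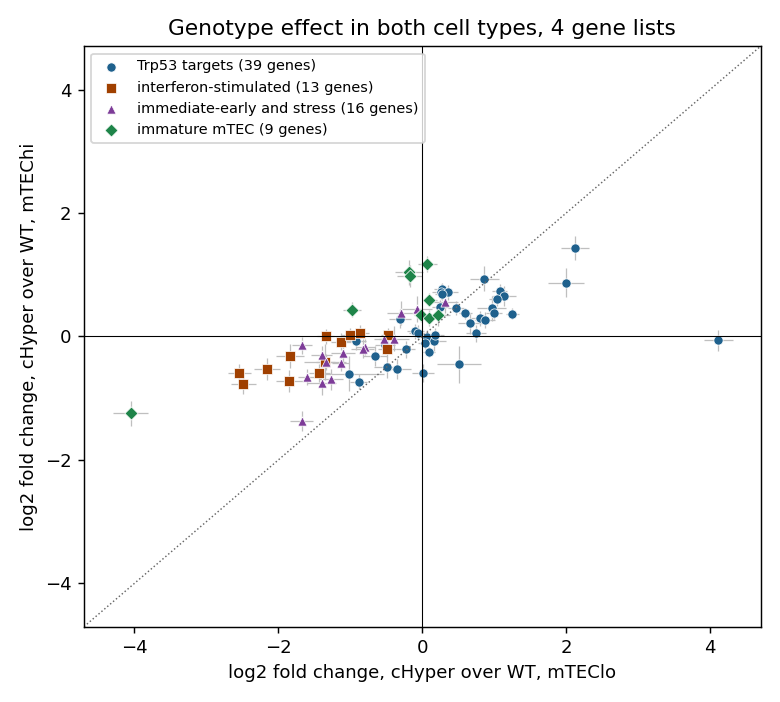
Log2 fold change of cHyper over WT in mTEClo (horizontal) and mTEChi (vertical) for the tested members of 4 gene lists; bars are standard errors and the dotted line marks equal change. Interferon-stimulated genes reach -2.54 in mTEClo (Irf7) and have a median of -0.32 in mTEChi, and Eda2r stands at 4.11 in mTEClo.

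The third comparison described what separates mTEChi from mTEClo in WT. Of 15 mature mTEC genes 14 rose, and 14 adjusted over the list alone (median log2 0.82, camera adjusted p = 0.000594, or 0.216 with an estimated correlation). Aire rose from 14.3 to 1919.9 CPM (135-fold), Cd86 from 0.264 ± 0.235 to 35.4 ± 9.72 (119-fold), Cd80 from 7.0 to 199.8 (28.6-fold), and Fezf2 2.99-fold. Of 9 immature mTEC genes 8 fell, and 8 adjusted over the list alone (median log2 -2.03, camera adjusted p = 4.6e-05, or 0.216 with an estimated correlation), with Ccl21a 19.9-fold, Krt14 9.14-fold and Pdpn 6.91-fold lower. Of the Aire-dependent antigens 8 of 9 rose and Wfdc18 fell, the same counts adjusted over the list alone (median log2 6.04, camera adjusted p = 0.0022, or 0.225 with an estimated correlation). The milk casein gene Csn2 rose from 5.22 ± 2.1 to 776 ± 29.7 CPM. Of the liver and pancreas antigens 19 of 20 rose and Crp fell from 133 ± 20.8 to 26 ± 2.03 CPM, the same counts adjusted over the list alone (median log2 5.92, or 5.28 with 3 members at their lower bound; camera adjusted p = 6.2e-05, or 0.216 with an estimated correlation).

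Tuft cell genes fell in WT mTEChi (11 of 12; median log2 -2.23, camera adjusted p = 4.6e-05), as did immediate-early genes (16 of 16; -1.31, 2.3e-06) and interferon-stimulated genes (11 of 13; -2.0, 1.5e-05). Irf7 was 8.49-fold, Jun 7.3-fold and Dclk1 6.65-fold lower. Enterocyte and hepatocyte genes (9 of 9 rose, camera adjusted p = 0.00119), neuroendocrine genes (10 of 11, 0.0133) and chemokines (7 of 8, 0.011) were higher. So were keratinocyte genes (10 of 11 rose and Krtdap fell, camera adjusted p = 0.0359) and secretory genes (6 of 7, 0.0359), the keratinocyte call ending without WT mTEChi replicate 1 (0.0547). These counts were the same adjusted over the list alone, and these list calls ended with an estimated correlation (camera adjusted p of 0.216 to 0.431). All 14 myeloid and dendritic markers rose, also adjusted over the list alone (median log2 4.86, camera adjusted p = 4.7e-05, or 0.0392 with an estimated correlation), with Lyz2 rising from 13.1 to 446 CPM and Adgre1 from 0.102 ± 0.0368 to 23.6 ± 2.06. B cell genes (5 of 5 rose, camera adjusted p = 0.0218, or 0.216 with an estimated correlation) and thymocyte genes (12 of 15, 0.0323, or 0.483) were higher too, with the same counts adjusted over the list alone. Whether the myeloid and dendritic, B cell and thymocyte transcripts came from such cells in the sort or from mTEChi themselves was not tested. Trp53 fell from 137 to 101 CPM (1.35-fold lower, edgeR adjusted p = 0.000281), whereas Cdkn1a rose 2.91-fold and Mdm2 1.89-fold. Of the Trp53 targets 19 rose and 13 fell, or 20 and 13 adjusted over the list alone (camera adjusted p = 0.894).

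The largest rises in WT mTEChi by the rule were genes with 0 fragments in WT mTEClo. They were at least 1042-fold (Fga, fibrinogen), 906-fold (Amtn), 546-fold (Clec4f), 527-fold (Alppl2), 497-fold (Adipoq, adiponectin), 464-fold (Slc17a6), 456-fold (Il22) and 449-fold (Tectb) higher. The largest falls were in the bitter taste receptor genes Tas2r102 (87.1-fold) and Tas2r118 (49.5-fold), then Tagln (36.1-fold), Gas1 (33.3-fold), Myl9 (30.7-fold), Scarf2 (30.3-fold), Mgp (28.3-fold) and Sult5a1 (26.1-fold). In all, 20119 genes were called by edgeR, 11626 higher and 8493 lower in mTEChi, and the groups did not overlap in 73.3% of genes, against 10% by chance. Library totals as scaling moved the median log2 change of all genes by 0.22 in WT and 0.17 in cHyper, so changes between the cell types are relative to that choice. The fit of replicates 1 and 2 alone called 19689, of which 19371 (98.4%) had the same direction in replicate 3.

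The fourth comparison repeated this in cHyper, where edgeR called 18648 genes, 11193 higher and 7455 lower in mTEChi. Aire rose 36.9-fold, Cd86 60.7-fold and Cd80 48.5-fold, and Krt14 fell 4.27-fold, Pdpn 6.01-fold and Ccl21a 8.54-fold. Of 15 mature mTEC genes 12 rose, or 13 adjusted over the list alone (camera adjusted p = 0.00212, or 0.23 with an estimated correlation). Of the immature mTEC genes 8 fell and Krt15 rose 8.16-fold, the same counts adjusted over the list alone (camera adjusted p = 0.000362, or 0.176 with an estimated correlation). Of the liver and pancreas antigens 19 rose and Crp fell, the same counts adjusted over the list alone (camera adjusted p = 6.8e-05, or 0.176 with an estimated correlation). Of the interferon-stimulated genes 9 fell and Usp18, Rsad2 and Mx1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.00652, or 0.394 with an estimated correlation), with Irf7 falling from 91.7 to 41.6 CPM. The myeloid and dendritic list passed with an estimated correlation here too (14 of 14 rose, also adjusted over the list alone; camera adjusted p = 6.8e-05, or 0.0333). The thymocyte list did not pass (camera adjusted p = 0.0769, or 0.595 with an estimated correlation) but did with the replicate block (0.0473), and that pairing did not hold without sex-linked genes. It also passed without WT mTEClo replicate 1 or 2 (0.0325 to 0.0374). Trp53 fell from 166 to 134 CPM (edgeR adjusted p = 0.0050), a call that ended with library totals as scaling (edgeR adjusted p = 0.143, the highest of a range from 0.00185 over the alternatives). Of the Trp53 targets 13 rose and 17 fell, also adjusted over the list alone (camera adjusted p = 0.188), and with library totals 14 rose and 13 fell.

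The largest rises in cHyper mTEChi by the rule were again from 0 fragments in mTEClo, at least 357-fold for Slc17a6, 330.5-fold for Zp3, 329.8-fold for Agtr2, 316-fold for Amelx, 266-fold for Mgat4c, 243-fold for Dppa1 and 243-fold for Reg3a. The largest falls were Sntn (22.3-fold), Thbd (18.8-fold), Dpp6 (17-fold), Lox (16.2-fold), Scarf2 (16-fold), Angptl4 (14.7-fold), Fzd2 (14.5-fold) and Rcn3 (14.4-fold). The groups did not overlap in 68.7% of genes, against 10% by chance. The same fit without replicate 3 called 18590, of which 17797 (95.7%) had the same direction in replicate 3. Across genes the changes between the cell types in WT and in cHyper, which share no library, had a Pearson correlation of 0.932 and a Spearman correlation of 0.936. In both genotypes 10368 genes rose (4498 for independent lists) and 6669 fell (2188). Deviations of same-numbered WT and cHyper libraries correlated, and the calls came from the same fit, so these lists were not independent either.

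**Figure D3:**
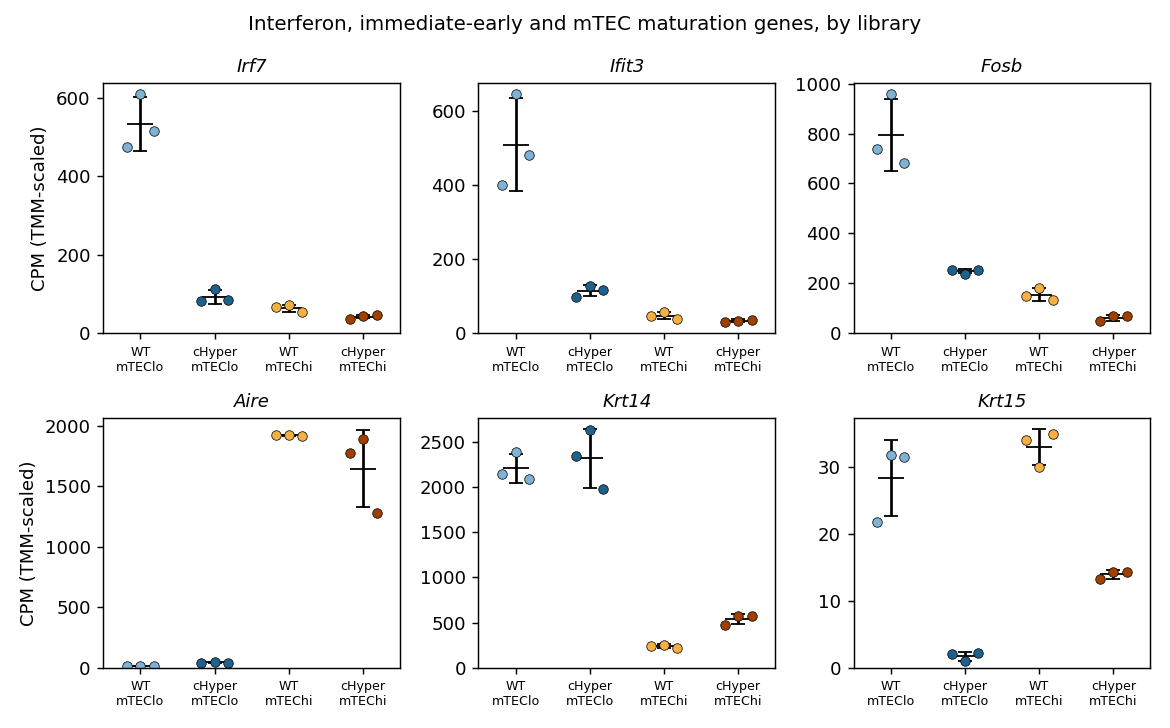
CPM on the TMM scale of 2 interferon-stimulated genes (Irf7, Ifit3), the immediate-early gene Fosb, Aire and the keratin genes Krt14 and Krt15; points are the 3 libraries of a group, the horizontal mark is their mean and the bar their SD. Irf7 falls from 533 to 91.7 CPM in mTEClo and Krt14 rises from 241 to 543 CPM in mTEChi.

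The number of genes detected at equal depth was the last measure. With at least 5 fragments among 22023800 per library, 28908 ± 193 genes were detected in WT mTEChi and 22833 ± 218 in WT mTEClo, a difference of 6075. In cHyper the difference was 4914 (27628 ± 399 against 22714 ± 604). Between the genotypes the difference in mTEChi was -1280, with fewer genes in cHyper in 3 of 3 same-numbered pairs. Each of these 3 differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. In mTEClo the difference between the genotypes was -119 (exact permutation p = 0.80), and its sign turned without cHyper mTEClo replicate 1 (86.7) or replicate 2 (21.2).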

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

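Results are listed here because a test of the difference itself found another genotype effect in mTEChi than in mTEClo. The test with genotype labels swapped, and the one on mTEClo-specific genes, both under the other observations, were chosen after the result was seen; the regroupings here were not.

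The edgeR test called 595 genes. Of 60 regroupings run of 200, 4 gave as many, the real one included (the highest other 2989). Those 4 all kept the real grouping of the mTEClo libraries and so carry the mTEClo genotype effect, so they do not decide whether chance is excluded for this count. The highest has the genotypes of all mTEChi libraries exchanged and so adds the genotype effects of the cell types. The structure of the samples behind its count therefore includes the genotype effect itself.

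The values below are log2 differences, mTEChi minus mTEClo. Upwards the largest by the rule for named genes were Gpr20 (4.42), Ms4a10 (3.7), C1ql2 (3.56) and Ms4a4d (3.5). Downwards they were Cpz (-8.36), Hbb-y (-5.95), Mroh7 (-5.72) and G6pc (-5.57). The last 3 rest on a group without fragments, so their fitted values are no bound. By the edgeR adjusted p the call of Ms4a4d ended without cHyper mTEChi replicate 2 (0.054) and that of G6pc without WT mTEClo replicate 1 or 2, cHyper mTEClo replicate 2 or 3 or cHyper mTEChi replicate 1, 2 or 3 (0.051 to 0.0768).

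The lists that differed were interferon-stimulated (median 1.05), immature mTEC (1.1), immediate-early and stress (0.64) and tuft genes (0.62), with mature mTEC (-0.20) and secretory genes (-0.55) lower (camera adjusted p of 2.0e-14, 5.1e-08, 4.2e-09, 0.000532, 0.0311 and 0.0456). By the camera adjusted p the call of the mature mTEC list ended without WT mTEClo replicate 1, cHyper mTEClo replicate 1 or 2, WT mTEChi replicate 2 or 3 or cHyper mTEChi replicate 1 (0.0653 to 0.144), with a median of -0.095 without WT mTEChi replicate 3. That of the secretory list ended without WT mTEClo replicate 1, cHyper mTEClo replicate 3, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1 or 2 (0.0521 to 0.307), with a median of -0.095 without cHyper mTEClo replicate 3, -0.92 without WT mTEClo replicate 2 and -0.97 without cHyper mTEClo replicate 1. With the replicate block the secretory list lost its call (camera adjusted p = 0.0588). The Trp53 target list passed with the block (camera adjusted p = 0.0422) but not without it (0.0609). With an estimated correlation camera passed 0 of the lists, and fry 3. Among interferon-stimulated genes Irf7 differed by 1.94, Mx1 by 1.72, Ifit3 by 1.63 and Ifit1 by 1.34. Among immediate-early and stress genes Hspb1 differed by 1.53, Atf3 by 1.1, Dusp1 by 0.94, Nr4a1 by 0.93 and Zfp36 by 0.70. Among immature mTEC genes Krt15 differed by 2.81, Ly6a by 1.42, Ccl21a by 1.22, Krt5 by 1.15 and Krt14 by 1.1. By the edgeR adjusted p the call of Zfp36 ended without WT mTEClo replicate 1 or 2, cHyper mTEClo replicate 1, 2 or 3, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1, 2 or 3 (0.062 to 0.109), that of Ccl21a without WT mTEClo replicate 3, cHyper mTEClo replicate 1, 2 or 3, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 2 or 3 (0.0508 to 0.0872) and that of Krt5 without cHyper mTEClo replicate 1 or 2, WT mTEChi replicate 1 or 3 or cHyper mTEChi replicate 2 or 3 (0.0544 to 0.0639).

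Trp53 targets that differed were Eda2r (-4.17), Zmat3 (-0.89) and Btg2 (0.84), and Aire differed by -1.87. Single members of other lists were Cxcl10 (1.59), Krtdap (1.91), Crp (1.24), Apob (-2.15), Myh8 (-1.54), Col3a1 (-1.94), Bpifb1 (-1.78), Alox5 (1.32), Ret (-0.98), Pcsk1 (1.58), Scg2 (1.48), Wfdc18 (1.24) and Tbata (-0.76). By the edgeR adjusted p several calls ended with 1 library left out. That of Btg2 ended without WT mTEClo replicate 1 or 2, cHyper mTEClo replicate 2 or 3, WT mTEChi replicate 2 or 3 or cHyper mTEChi replicate 1 or 3 (0.0548 to 0.0914), of Apob without WT mTEClo replicate 1, 2 or 3, cHyper mTEClo replicate 2 or 3, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1, 2 or 3 (0.0539 to 0.137) and of Myh8 without WT mTEClo replicate 2 or 3, cHyper mTEClo replicate 1 or 2, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 2 or 3 (0.0601 to 0.0851). That of Bpifb1 ended without WT mTEClo replicate 1, WT mTEChi replicate 2 or 3 or cHyper mTEChi replicate 2 or 3 (0.0513 to 0.0675), of Alox5 without WT mTEClo replicate 1 or 3, WT mTEChi replicate 2 or 3 or cHyper mTEChi replicate 1 or 3 (0.0521 to 0.0944) and of Pcsk1 without WT mTEClo replicate 1, cHyper mTEClo replicate 1 or 2, WT mTEChi replicate 2 or 3 or cHyper mTEChi replicate 1 or 2 (0.0512 to 0.0766). That of Scg2 ended without WT mTEClo replicate 1 or 3, cHyper mTEClo replicate 1 or 2, WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 1, 2 or 3 (0.0646 to 0.106), of Wfdc18 without WT mTEClo replicate 2 or 3, cHyper mTEClo replicate 1 or 2, WT mTEChi replicate 1, 2 or 3 or cHyper mTEChi replicate 1 or 3 (0.0529 to 0.0957) and of Tbata without WT mTEClo replicate 2 or 3, cHyper mTEClo replicate 1 or 3, WT mTEChi replicate 1 or 2 or cHyper mTEChi replicate 3 (0.0548 to 0.0764). With all libraries kept, the edgeR adjusted p ended the calls of Btg2 (0.0529), Alox5 (0.0534), Scg2 (0.0572), Wfdc18 (0.0628) and Apob (0.0568) with library totals, of Scg2 (0.0503), Wfdc18 (0.0514) and Apob (0.0514) with DESeq2 size factors, of Wfdc18 (0.0526) and Apob (0.0514) at 1 CPM or more in 3 libraries and of Apob (0.0534) with the replicate block. The limma-voom adjusted p ended those of Bpifb1 (0.0608), Pcsk1 (0.0512), Apob (0.201) and Myh8 (0.0857).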

How the results depend on the processing

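No alternative was chosen after seeing the data except adjustment over genes with a fragment in the compared groups, which gave 2704 genes in mTEClo and 572 in mTEChi. For values given below the cause was not tested, unless fewer libraries or a stricter test gives it.

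Between genotypes in mTEClo the count stayed within 1.5 times 2651, except against a fold of 1.5 (563). In mTEChi 572 became 1396 with DESeq2, 862 with limma-voom, 1126 with only the compared groups, 1251 with the replicate block, 963 with a term for replicate 3, 312 in replicates 1 and 2 and 42 against a fold of 1.5. With 1 library left out it ran from 296 (cHyper mTEChi replicate 3) to 678 (cHyper mTEClo replicate 3). The share of higher genes was 63% at 1 CPM or more in 3 libraries (353 higher, 207 lower). For the difference between effects 595 became 1103 without the filter, 1406 with DESeq2, 1186 with the replicate block, 965 with a term for replicate 3, 282 in replicates 1 and 2 and 131 against a fold of 1.5. With 1 library left out it ran from 354 (WT mTEChi replicate 2 or cHyper mTEChi replicate 2) to 629 (WT mTEClo replicate 2). Between cell types every alternative stayed within 1.5 times 20119 in WT and 18648 in cHyper.

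In mTEClo and in WT the lowest same-numbered correlation missed the cut of 0.1 (0.0972 and 0.093), so these were not treated as paired. The other correlations were 0.18 and 0.171 in mTEClo and 0.172 and 0.233 in WT, above the highest in cHyper (0.125). Each library also correlated best with its own number, so a pairing in mTEClo and in WT is not excluded. The block gave 3916 genes in mTEClo and 20972 in WT. In the 2 comparisons treated as paired, the block changed no call of a named gene, and no other count or list than those given. For the difference between effects it ended the calls of Apob and of the secretory list, and the Trp53 target list passed. The single-run, 20-sample and run-agreement alternatives were not run, as runs are combined.

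Lists past the threshold were 8, 5, 15, 17 and 6 (genotype in mTEClo, in mTEChi, cell types in WT, in cHyper, difference). With an estimated correlation camera passed 0, 0, 1, 1 and 0; fry passed 10, 2, 23, 21 and 3, in mTEClo with the mature and immature mTEC, muscle and endothelial lists, which camera did not pass. With 1 library left out they were 3 to 6 in mTEChi (3 without cHyper mTEChi replicate 1 or 2) and 4 to 11 for the difference (11 without WT mTEClo replicate 2).

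The extra genes of mTEChi were 5149.7 in WT and 4334 in cHyper at 10 fragments or more, and 5221 and 4317 at 0.5 times the depth. In mTEClo the genotype difference ran from -466 to 86.7, and turned without cHyper mTEClo replicate 1 or replicate 2 (21.2).

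Of 262 results for named genes 249 were called. Over 20 alternatives, 202 never lost the call, 47 lost it somewhere and 0 turned sign by edgeR, DESeq2 or limma-voom. An alternative in which a gene was filtered out or had no adjusted p was passed over for that gene. Left out of these 20 were the test against a fold, the fit without the filter and replicates 1 and 2 alone. How many calls of named genes would end under those was not counted. Reversed values were log2 changes of uncalled genes. Fezf2 ran from -0.16 to 0.0036 (without WT mTEChi replicate 3 and 2) in mTEChi and from -0.0060 to 0.29 (without cHyper mTEClo replicate 3 and 1) for the difference. Lyz2 ran from -0.073 to 0.65 in mTEClo and -0.16 to 0.078 in mTEChi. Csf1r ran from -0.10 to 0.041 in mTEClo, and was 0.0015 with limma-voom.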

Other observations

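The test with genotype labels swapped and the test on mTEClo-specific genes in cHyper mTEChi were chosen only after the result was seen, as were the thresholds that define specific genes and the simulated bounds.

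For the pairwise counts, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 2651 genes between genotypes in mTEClo (the highest other 2), 572 in mTEChi, 20119 between cell types in WT and 18648 in cHyper (the highest other 0 in each, by edgeR), with 1 split as large in each. Within 10 Mb of Trp53 lay 2.1% of the genes called in mTEChi, against 1.65% of tested genes. This argues against sequence differences around Trp53 as the main source of those calls. Where the cHyper allele lies is not given in the sources used here, so sequence differences around another locus stay open.

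Interferon-stimulated genes were lower in cHyper mTEClo (median log2 -1.35). Fewer myeloid and dendritic cells in those libraries would lower their markers as far, but the median of that list was -0.0022, with its most abundant members in WT mTEClo, Csf1r and Lyz2, at 14.7 and 14.7 CPM and at 13.1 and 17.6. C1qb, at 0.631 and 0.275 CPM, did fall about as far (log2 -1.32, or -0.86 without cHyper mTEClo replicate 1), while Irf7 went from 533 to 91.7. EpCAM enrichment and sorting are meant to remove such cells, but how far they did was not tested. Replicates 1 and 2 alone gave a median of -1.44, which argues against replicate 3 as the carrier. An effect of the genotype may underlie the fall, and exposure of the WT mice, a day of sorting or litters that followed genotype stay open, since the labels give none of these.

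Aire was higher in cHyper mTEClo, while the lists of Aire-dependent antigens and of liver and pancreas antigens did not pass there. A share of mTEChi RNA would raise all genes specific to mTEChi by about 1 fraction of their mTEChi level. Of 898 such genes 62.9% were higher in cHyper mTEClo (simulated lower bound for a uniform share 67.7%), with a median implied share of 0.592% and quartiles of -0.968% and 2.17%. The distance to the bound is small. The reference was WT mTEChi, while mTEChi cells in those libraries would be cHyper. Some specific genes, such as Scg2, were themselves lower in cHyper mTEClo and would fall short of a uniform share. The test therefore does not decide on a share of mTEChi RNA in cHyper mTEClo. In cHyper mTEChi, 72.3% of 559 mTEClo-specific genes were higher (bound 87.5%), with a median of 2.64% and quartiles of -0.323% and 5.58%. The reference there was WT mTEClo, while mTEClo cells in those libraries would be cHyper. Interferon-stimulated and immediate-early genes were lower in cHyper mTEClo, so some specific genes would fall short of a uniform share. The test therefore does not decide on a share there. A share of mTEClo RNA, changes within the cells or a gate set differently could contribute.

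Cdkn1a was lower in cHyper while other Trp53 targets were higher. In mTEClo 16 called targets rose and 4 fell, but these counts are part of the pattern, and no source used here states which way cHyper moves Trp53 activity, so exchanged genotype labels stay open. The choice of scaling did not carry the fall, since over both cell types its log2 change nearest to 0 under another scaling was -0.79, and at the least it kept 102% of its reported size. A Trp53 form or dose that acts differently on Cdkn1a than on other targets may be at work, and so may other regulators of Cdkn1a; neither was tested.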
